A study of Homo sapiens with 12 samples.

How the data were processed

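Gene expression was measured in L540 cells, a CD30-positive Hodgkin lymphoma line, on Illumina HumanHT-12 v3 BeadChips with 12 arrays in 6 groups of 2 biological duplicates. The groups were untreated cells and cells given CD30L-Fc (CD153-Fc) or the anti-CD30 monoclonal antibody T104, T427, T408 or PW30, at 10 µg/ml per the labels, after 16 h of preculture. The series design text gives 8 h of treatment and states that the 24 h in the sample labels is wrong, while the growth protocol still gives 24 h. The same text names an antibody T428 where the sample labels have T408, and the name T408 is used here. RNA was extracted with TRI reagent and labelled as biotinylated cRNA. Whether the untreated cells received the carrier solution is not given in the sources used here.

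Per the labels the authors processed the scans with GenomeStudio, and the series design text names BeadStudio. Versions are not given in the sources used here. The deposited table before normalization holds, per array, a signal intensity for each of 48780 probes and, per the file headers, a detection p-value against the negative control beads. The authors' processed table holds linear signal intensity without background subtraction. Its columns have medians of 138.9 to 139.0 and sorted values that differ by an SD of at most 0.480%, so it was read as quantile-normalised, a step the labels do not name. Probes were linked to genes through the probe annotation supplied with the series. Of the 48780 probes 28082 carried 1 gene, 13 several and 20685 none. Of the symbols, 28043 were updated through their Entrez identifier against the RefSeq gene table of assembly GRCh38.p14 and 39 were kept as given. That table also gave the genomic span of each gene. No coordinates are printed.

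Signals before normalization were background-corrected with the normexp model, with the moments of the negative controls inferred from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalised and put on the log2 scale, as in limma's neqc (limma 3.58.1, R 4.3.3). Probes with a detection p below 0.01 on both arrays of at least 1 group were kept (11949), and the brightest probe per gene was used, which left 8113 genes. A linear model with 6 group means was fitted over all 12 arrays with lmFit and eBayes, so that all groups share 1 estimate of the spread. Each of 15 comparisons (5 treatments against untreated, 4 antibodies against CD30L-Fc and 6 antibody pairs) was tested two-sided, with Benjamini-Hochberg adjustment within the comparison and a call at an adjusted p below 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333. Intervals are at 95%. The number of arrays limits the precision.

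The 27 gene lists, the 15 comparisons and their tests, the rule for naming genes and most alternatives were fixed before the data were examined, and what was added later is marked where it stands. The lists were NF-kB subunits and regulators, chemokines and chemokine receptors, cytokines and cytokine receptors, the TNF and TNF receptor superfamily, adhesion, costimulation and activation surface molecules, anti-apoptotic genes, pro-apoptotic genes, G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors and p53 targets, AP-1 and immediate early genes, interferon-stimulated genes, antigen presentation, the JAK-STAT pathway and its feedback inhibitors and lymphoid transcription factors. Further lists were T cell, cytotoxic granule, B cell, monocyte and macrophage, and fibroblast and epithelial markers, the unfolded protein and amino acid response, heat shock proteins, glycolysis and hypoxia, cholesterol synthesis, the oxidative stress response, ribosomal proteins and housekeeping genes. Lists with at least 5 measured members (22) were tested with limma's camera with a preset inter-gene correlation of 0.01 and adjusted over the lists within a comparison. The test was repeated with an estimated correlation and with fry. For the NF-kB list the estimate was 0.0135, near the preset value, yet the camera p after CD30L-Fc went from 4.15e-26 to 4.81e-05. A larger p with the estimate therefore need not mean that the members are correlated.

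Genes were named by a fixed rule. For each treatment against untreated cells these were the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, and up to 4 called members of each list with the smallest p. For the other comparisons they were the 5 largest in each direction, or the 3 with the smallest p where 0 genes were called. TNFRSF8 was always included. The rule took 125 genes.

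Because all treatments share the 2 untreated arrays, the correlation, covariance and overlap of log2 changes are printed beside values from 100 simulated experiments with unchanged groups and beside the overlap of independent lists. On simulated data for T104 against untreated with 8113 genes, limma recovered 16% of genes changed by a log2 of 0.5, 96% at 1, 100% at 2 and 100% at 3, and 8 of 164 calls were false. There camera called 0 of 20 random lists. Each gene was drawn independently, so this does not show how camera treats lists with correlated members.

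The alternatives were no background correction, an offset of 50, median scaling, the authors' processed values, no filter on dim probes, detection on all 12 arrays, every probe on its own, a trend and robust variance prior, the 4 arrays of the 2 groups alone, replicate number as a block, adjustment over all 15 comparisons, and each array left out in turn. A fit without the PW30 arrays was added after the data had been seen. Adjustment over all 15 comparisons pools their p-values under a single cutoff. It does not limit the share of false calls within a comparison with few changes. A block for the BeadChip slide was not run, since the files used show no slide.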

Results

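L540 is an established Hodgkin lymphoma cell line that carries CD30 (TNFRSF8), a member of the TNF receptor superfamily, on its surface. The series compared gene expression in L540 cells given the CD30 ligand, as a fusion protein with an Fc part (CD30L-Fc), or 1 of 4 monoclonal antibodies that recognise distinct CD30 epitopes (T104, T427, T408 and PW30). The 12 BeadChip arrays fell into 6 groups of 2 biological duplicates, namely untreated cells and the 5 treatments. The median signal per array before normalization lay between 129.9 and 151.7, and 10910 to 12005 probes per array were detected. That median differed by group. It was 144.0 or more on the untreated and CD30L-Fc arrays and 136.3 or less on the T427, T408 and PW30 arrays. Pearson's r across probes between duplicates lay between 0.990 and 0.993. Across the arrays, the first principal component held 44.3% of the variance and set the CD30L-Fc, T104 and PW30 arrays apart from the untreated, T427 and T408 arrays. The second held 11.3% and set both PW30 arrays (scores of -0.56 and -0.52) apart from the other arrays. No arm with a control antibody or a control Fc protein was analysed here. Changes are log2 differences between group means with the standard error (SE) from limma, n = 2 arrays per group. The number of arrays limits their precision.

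The first question was what CD30L-Fc changed in the cells. TNFRSF9, a costimulatory receptor of the TNF receptor superfamily, rose most, by a log2 of 3.90 ± 0.15 or 14.9-fold (adjusted p = 3.05e-08). TRAF1, an adaptor of TNF receptor signalling, rose by 3.46 ± 0.19, and RELB, an NF-kB subunit, by 3.13 ± 0.11. IL4I1, a secreted amino acid oxidase, rose by 2.86 ± 0.14, LTA, which encodes lymphotoxin alpha, by 2.82 ± 0.12, EBI3, a subunit of heterodimeric cytokines, by 2.65 ± 0.14, and TUBB2A, a beta-tubulin, by 2.65 ± 0.12. CD80, a costimulatory ligand for T cells, rose at least 2.44-fold (adjusted p = 2.3e-07), the cytokine gene IL15 at least 3.26-fold (adjusted p = 2.11e-06) and the surface receptor gene SLAMF1 at least 3.78-fold (adjusted p = 4.28e-06). Among genes that fell, EVA1A, a regulator of autophagy, changed by -2.28 ± 0.17, CD93, a surface glycoprotein, by -2.05 ± 0.17, and GPR183, an oxysterol receptor that guides lymphocyte migration, by -1.64 ± 0.13. An "at least" fold is given where no probe of the gene was detected on either array of a group, and sets its level there no lower than that of the dimmest detected probe on each array. In all, 676 of 8113 genes passed the limma test at an adjusted p below 0.05, of which 443 rose and 233 fell, and 159 rose and 38 fell at least 2-fold. A fit with the 4 arrays of the 2 groups alone called 402 genes, and the counts were 439 without CD30L-Fc replicate 1 and 372 without replicate 2.

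Of the lists of related genes, the NF-kB subunits and regulators had the smallest camera p after CD30L-Fc, where 15 of 19 measured members rose, 0 fell and 4 did not pass, with a median log2 of 1.04. The inhibitors of the pathway NFKBIA (2.62 ± 0.13) and TNFAIP3 (2.54 ± 0.14) were among them. In the TNF and TNF receptor superfamily 7 of 16 rose, 0 fell and 9 did not pass, among them CD70, the ligand of CD27 (2.47 ± 0.21), and TNF (1.86 ± 0.19). Of the 5 measured chemokines and chemokine receptors 4 rose, among them CXCR4 (1.80 ± 0.17), CCL5 (1.29 ± 0.12) and CXCL10 (at least 1.52-fold). Their median was 1.80, or 0.60 with genes not well above background at their bounds. Of 11 cytokines and cytokine receptors 4 rose, such as IL21R (1.38 ± 0.13), and 1 fell. Of 10 adhesion, costimulation and activation molecules 5 rose, such as CD83 (2.27 ± 0.12), and of 9 anti-apoptotic genes 4 rose, among them CFLAR (2.46 ± 0.16) and BCL2L1 (1.47 ± 0.13). Of 15 AP-1 and immediate early genes 6 rose, such as KLF6 (1.62 ± 0.19) and DUSP1 (1.27 ± 0.13), of 21 antigen presentation genes 5 rose, such as TAP1 (0.83 ± 0.11), and of 11 cholesterol synthesis genes 3 rose, such as INSIG1 (1.44 ± 0.16) and HMGCS1 (0.94 ± 0.13). Adjusted over the list alone, 17 NF-kB genes, 10 TNF superfamily genes (2 fell), 5 chemokine genes, 5 cytokine genes (1 fell), 5 adhesion genes, 4 anti-apoptotic genes, 6 AP-1 genes, 8 antigen presentation genes and 3 cholesterol synthesis genes rose. In limma's camera test these 9 lists were higher on average than the other genes, with adjusted p from 9.14e-25 to 0.00322. All 9 also passed with an estimated correlation. Such an average can rest on part of the members. In the anti-apoptotic list the mean log2 was 0.54 and the median 0.085, with 6 of 9 members positive. In the JAK-STAT list 5 of 17 rose and 1 fell (6 and 1 adjusted over the list alone), with STAT5A (1.54 ± 0.16) and TYK2 (0.97 ± 0.15) the strongest. Its camera adjusted p was 0.0106, and its adjusted p was 0.0738 with an estimated correlation.

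T104 addressed the same question for an antibody. TNFRSF9 rose by a log2 of 4.02 ± 0.15 (adjusted p = 2.1e-08), TRAF1 by 3.64 ± 0.19, RELB by 3.09 ± 0.11, IL4I1 by 2.92 ± 0.14, EBI3 by 2.86 ± 0.14 and LTA by 2.81 ± 0.12. CD80 rose at least 2.82-fold (adjusted p = 1.38e-07), and GPR84, a receptor for medium-chain fatty acids, at least 3.17-fold (adjusted p = 1.13e-06). EVA1A fell at least 3.85-fold (adjusted p = 5.73e-07). SMIM43 changed by -1.88 ± 0.14, GPR183 by -1.73 ± 0.13, and ATXN1, a transcriptional regulator, by -1.46 ± 0.20. Of 8113 genes, 480 rose and 286 fell (766 in all), 175 and 45 of them at least 2-fold. The count was 487 with only the 4 arrays of the 2 groups, 500 with no filter on dim probes, 425 without T104 replicate 1 and 453 without T104 replicate 2.

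After T104, 15 of 19 NF-kB genes rose, 0 fell and 4 did not pass (17 rose adjusted over the list alone), with a median of 1.17. In the TNF superfamily 9 of 16 rose (10 adjusted over the list alone), including CD70 (2.46 ± 0.21), and 4 of 5 chemokine genes rose (5 adjusted over the list alone), including CXCL10 (at least 2.15-fold) and CCL17 (at least 1.64-fold). The counts that rose were 4 of 11 cytokine genes, 5 of 10 adhesion genes, 4 of 9 anti-apoptotic genes, 5 of 15 AP-1 genes, 4 of 21 antigen presentation genes and 3 of 11 cholesterol synthesis genes (6, 5, 4, 6, 9 and 3 adjusted over the list alone). These 9 lists were raised in camera with either correlation. In 3 further lists the call was lost with an estimated correlation, of 0.0140 (JAK-STAT), -0.0491 (G2/M and mitosis) and 0.0205 (unfolded protein response). Of 17 JAK-STAT genes 5 rose and 1 fell, STAT4 by -0.71 ± 0.13 (6 and 2 adjusted over the list alone), with a camera adjusted p of 0.0363 and an adjusted p of 0.117 with an estimated correlation. Of 18 G2/M and mitosis genes 2 fell and 0 rose, also adjusted over the list alone, with a median of -0.16, a camera adjusted p of 0.0363, and an adjusted p of 0.0991 with an estimated correlation. Of 17 unfolded protein response genes 2 rose (3 adjusted over the list alone), with a camera adjusted p of 0.0254 and an adjusted p of 0.113 with an estimated correlation. One of these was HSPA5, an endoplasmic reticulum chaperone (0.77 ± 0.17, adjusted p = 0.0127), which no longer passed without untreated replicate 1, T104 replicate 1 or T104 replicate 2 (log2 from 0.57 to 0.96 over all alternatives).

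PW30 called the most genes of the 5 treatments. TNFRSF9 rose by 3.84 ± 0.15 (adjusted p = 3.62e-08), TRAF1 by 3.47 ± 0.19, RELB by 3.31 ± 0.11, IL4I1 by 2.84 ± 0.14, LTA by 2.83 ± 0.12 and TNFAIP3 by 2.78 ± 0.14. GPR84 rose at least 3.72-fold (adjusted p = 6.85e-07). EVA1A fell at least 4.74-fold (adjusted p = 1.61e-06), and the phosphatase gene PTPRO at least 2.19-fold (adjusted p = 1.26e-04). ARID5B, a chromatin regulator, changed by -1.74 ± 0.13, GPR183 by -1.66 ± 0.13 and SMIM43 by -1.64 ± 0.14. Of 8113 genes, 509 rose and 389 fell (898 in all), 170 and 55 of them at least 2-fold. With median scaling in place of quantile normalization, which moved the median of all genes from -0.05 to -0.13, 362 rose and 569 fell. The count was 490 with only the 4 arrays of the 2 groups, 546 with no filter on dim probes and 562 without PW30 replicate 1.

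After PW30, 14 of 19 NF-kB genes rose, 0 fell and 5 did not pass (17 rose adjusted over the list alone), with a median of 1.24. In the TNF superfamily 9 of 16 rose and 1 fell, also adjusted over the list alone, with CD70 at 2.71 ± 0.21. The counts that rose were 4 of 5 chemokine genes, 5 of 11 cytokine genes, 4 of 10 adhesion genes, 4 of 9 anti-apoptotic genes, 6 of 15 AP-1 genes, 6 of 21 antigen presentation genes and 4 of 11 cholesterol synthesis genes (5, 6, 5, 5, 7, 7 and 4 adjusted over the list alone). IL32, a cytokine gene, rose by 1.23 ± 0.12, and PSME1, a proteasome activator subunit, by 0.77 ± 0.15, while 1 cytokine gene fell, also adjusted over the list alone. These 9 lists were raised in camera with either correlation. In the G2/M and mitosis list 1 of 18 fell, also adjusted over the list alone, namely the kinesin gene CENPE (-0.68 ± 0.13), with a median of -0.15. Its camera adjusted p was 0.0290, and its adjusted p was 0.0803 with an estimated correlation. The JAK-STAT list, with 4 of 17 raised and 2 lowered (5 and 2 adjusted over the list alone), did not pass (adjusted p = 0.111). Both PW30 arrays stand apart on the second principal component, which holds for every PW30 value given here.

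**Figure D1:**
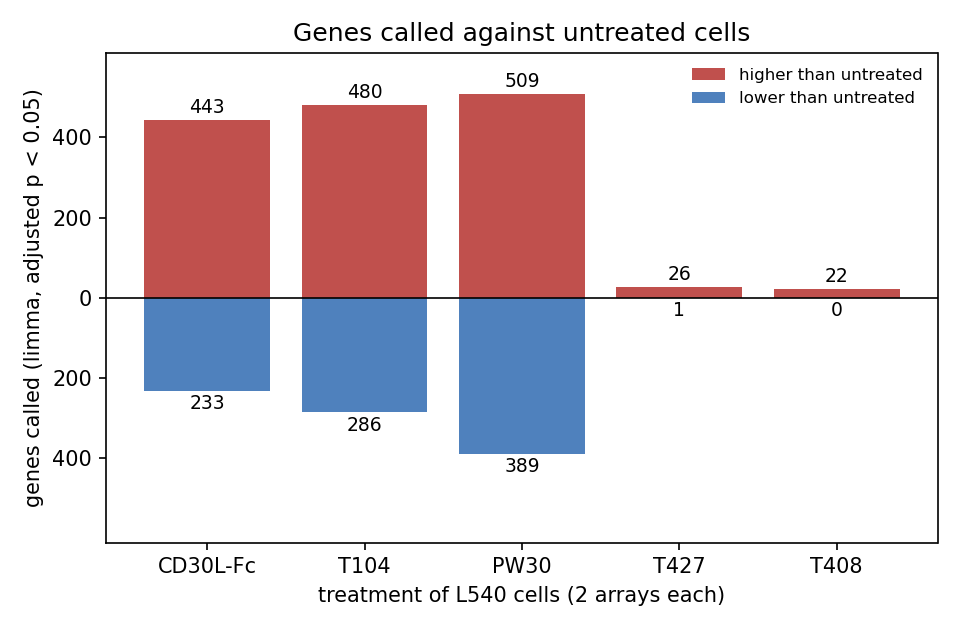
Number of genes called higher (red, upward) or lower (blue, downward) than in untreated cells for each treatment, by limma over 8113 genes with 2 arrays per group. CD30L-Fc, T104 and PW30 called 676, 766 and 898 genes, against 27 for T427 and 22 for T408.

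T427 raised a small set of genes. TRAF1 rose by 1.71 ± 0.19 (adjusted p = 0.00138), RELB by 1.53 ± 0.11 (adjusted p = 1.16e-04), IL4I1 by 1.47 ± 0.14, TNFRSF9 by 1.46 ± 0.15 and NFKB2, a further NF-kB subunit, by 1.29 ± 0.13. These 5 genes passed under every alternative. Among the 19 NF-kB genes 7 rose, 0 fell and 12 did not pass (9 rose adjusted over the list alone), with a median of 0.34, a camera adjusted p of 2.12e-22 and an adjusted p of 0.00142 with an estimated correlation. Of 5 chemokine genes 1 rose (2 adjusted over the list alone), namely CXCR4 (1.19 ± 0.17), which did not pass with the 4 arrays alone, without untreated replicate 2 or without T427 replicate 2 (log2 from 1.03 to 1.36 over all alternatives). That list had a camera adjusted p of 0.0206, and an adjusted p of 0.212 with an estimated correlation. CD70 differed from untreated cells by 0.00 ± 0.21 and EBI3 by 0.26 ± 0.14, neither called. The 1 gene that fell was TMEM214, by -0.68 ± 0.12 (adjusted p = 0.0378), and it did not pass under 12 of 16 alternatives, among them those without untreated replicate 2, T427 replicate 1 or T427 replicate 2. In all 27 of 8113 genes passed, 26 of them higher and 12 at least 2-fold. The count was 5 with the 4 arrays alone, 10 with no filter on dim probes and 63 (47 higher, 16 lower) with the adjustment over all 15 comparisons, and 16, 8 and 12 without T427 replicate 1 (13 higher, 3 lower), T427 replicate 2 or untreated replicate 2.

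T408 also raised few genes. TRAF1 rose by 1.82 ± 0.19 (adjusted p = 8.16e-04), RELB by 1.75 ± 0.11 (adjusted p = 2.63e-05), IL4I1 by 1.51 ± 0.14, TNFRSF9 by 1.45 ± 0.15 and NFKBIA by 1.25 ± 0.13, and TNFAIP3 rose 2.23-fold (adjusted p = 0.00251). ANK3, which encodes a membrane skeleton adaptor, rose at least 1.27-fold (adjusted p = 8.16e-04). These 7 genes passed under every alternative that tested them, where ANK3 was left untested by detection on all 12 arrays. In the NF-kB list of 19 genes 6 rose, 0 fell and 13 did not pass (9 rose adjusted over the list alone), with a median of 0.35, a camera adjusted p of 5.03e-19 and an adjusted p of 0.00227 with an estimated correlation. Of 10 adhesion and costimulation genes 1 rose (2 adjusted over the list alone), CD83 by 0.99 ± 0.12, with a camera adjusted p of 0.0385 and an adjusted p of 0.262 with an estimated correlation. CD83 did not pass with the 4 arrays alone (log2 from 0.90 to 1.05 over all alternatives). CD70 differed by 0.18 ± 0.21 and EBI3 by 0.46 ± 0.14, neither called. In all 22 of 8113 genes passed, 22 higher and 0 lower, 14 at least 2-fold. By limma 648 genes had an unadjusted p below 0.05, where 406 would be expected by chance. The count was 9 with the 4 arrays alone, 13 with no filter on dim probes, 34 with the authors' processed values or with no background correction, 41 with a trend in the variance prior, 72 (56 higher, 16 lower) with the adjustment over all 15 comparisons and 14 without T408 replicate 2. Without T408 replicate 1 it was 17 (14 higher, 3 lower).

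**Figure D2:**
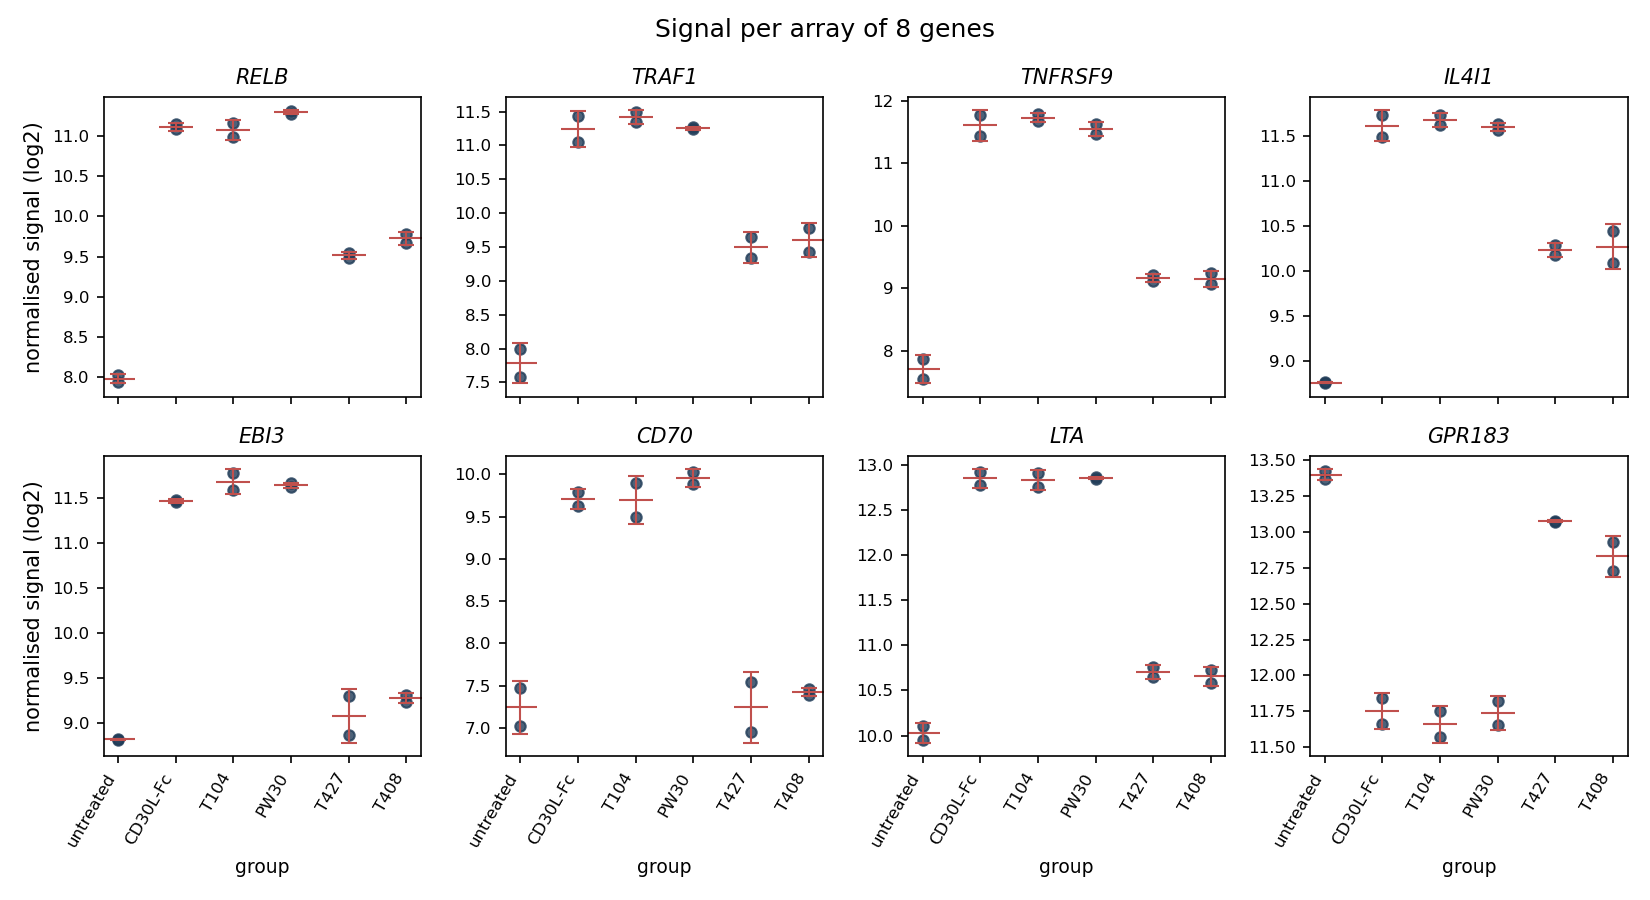
Normalised log2 signal (vertical axis) of 8 genes on each of the 12 arrays (points), with the group mean and SD (red bars, n = 2), by group (horizontal axis). RELB rose by 3.13 after CD30L-Fc and by 1.53 after T427, whereas CD70 rose by 2.47 after CD30L-Fc and differed by 0.00 after T427.

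The other lists did not pass camera in any of the 5 treatments, and 0 of their members were called after T427 or T408. Each range of adjusted p given for these other lists covers all 5 treatments, also where the counts beside it cover only CD30L-Fc, T104 and PW30. For the lists described above, the treatments not yet given did not pass. The adjusted p was 0.131 after CD30L-Fc for the G2/M list (0 of 18 rose or fell), and 0.0625 and 0.124 after CD30L-Fc and PW30 for the unfolded protein response list (2 and 1 of 17 rose, 3 and 1 adjusted over the list alone). After T427, 2 of 16 TNF superfamily genes, 1 of 10 adhesion genes and 1 of 9 anti-apoptotic genes rose, and after T408 1 of 16 TNF superfamily, 1 of 5 chemokine and 1 of 11 cytokine genes did, with adjusted p of 0.0572 or more. Adjusted over the list alone, 2 TNF superfamily, 2 cytokine, 1 adhesion and 1 anti-apoptotic gene rose after T427. There 1 TNF superfamily and 1 interferon-stimulated gene fell. After T408, 2 TNF superfamily, 1 chemokine, 3 cytokine, 1 anti-apoptotic and 1 AP-1 gene rose in that way, and 1 AP-1 gene fell. The inhibitor CDKN1A rose by 1.19 ± 0.17, 1.19 ± 0.17 and 1.27 ± 0.17 after CD30L-Fc, T104 and PW30, and passed under every alternative. It belongs to the 17 measured cell cycle inhibitors and p53 targets, of which 2, 1 and 4 rose and 0, 0 and 1 fell (2, 2 and 4, and 0, 0 and 2 adjusted over the list alone), with a camera adjusted p of 0.211 to 0.376. Among 16 interferon-stimulated genes 3 rose and 1 fell in each of these 3 treatments (4, 3 and 4 rose and 1 fell adjusted over the list alone), with an adjusted p of 0.0625 to 0.269. IRF1, an interferon regulatory factor, rose by 1.30 ± 0.14, 1.37 ± 0.14 and 1.38 ± 0.14, while IFI44L changed by -0.85 ± 0.14 after CD30L-Fc and fell at least 1.53-fold after T104 and at least 1.89-fold after PW30. Among 11 lymphoid transcription factors 3, 2 and 2 rose and 2, 1 and 1 fell (3, 3 and 2, and 4, 4 and 1 adjusted over the list alone), with GATA3 at 0.75 ± 0.14 after T104 and an adjusted p of 0.688 to 0.963. Among 9 pro-apoptotic genes 0 rose, and 0, 1 and 0 fell (0, 3 and 0 adjusted over the list alone), with an adjusted p of 0.0747 to 0.878. Of 14 G1/S and DNA replication genes 2, 1 and 2 rose and 0, 0 and 2 fell, also adjusted over the list alone (adjusted p from 0.575 to 0.963). Of 16 glycolysis and hypoxia genes 2, 1 and 2 rose (2, 2 and 2 adjusted over the list alone) and 1 fell each time, ANKRD37 by -0.79 ± 0.14 after CD30L-Fc (adjusted p of the list from 0.643 to 0.955). Of 11 heat shock proteins 1, 1 and 0 rose (2, 1 and 0 adjusted over the list alone), with an adjusted p of 0.570 to 0.927. Of 11 oxidative stress genes 0, 0 and 1 rose, also adjusted over the list alone, with an adjusted p of 0.676 to 0.963. None of 16 ribosomal protein genes and 10 housekeeping genes was called, with an adjusted p of 0.299 to 0.974 and 0.575 to 0.912. None of the 36 list results called against untreated cells turned direction or was lost under the 4 other scalings.

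Most of the listed cell type markers did not pass the detection filter, which 8113 of 18846 genes passed. Of the listed genes, 4 of 16 T cell markers, 4 of 10 cytotoxic granule genes, 2 of 14 B cell markers, 2 of 14 monocyte and macrophage markers and 0 of 12 fibroblast and epithelial markers were measured, too few for camera. SRGN, which encodes a granule proteoglycan, rose by 1.01 ± 0.13 after CD30L-Fc and 1.28 ± 0.13 after PW30, and 2.22-fold after T104. CD247, a T cell receptor subunit, rose by 0.48 ± 0.13 after CD30L-Fc (adjusted p = 0.0401), and did not pass under 7 of 16 alternatives, among them those without untreated replicate 1, CD30L-Fc replicate 1 or CD30L-Fc replicate 2. Adjusted over the list alone, CD247 also rose after T104 and PW30, and both measured monocyte and macrophage markers rose after T104, CSF1R by 0.27 ± 0.11 and CD68 by 0.50 ± 0.20. Neither of the 2 passed over all genes (adjusted p = 0.175 and 0.168), and no B cell or monocyte marker did in any treatment. CD30 itself (TNFRSF8) was detected on both untreated arrays at a log2 signal of 7.46 (SD 0.19). It differed from untreated cells by -0.07 after CD30L-Fc, -0.05 after T104, -0.26 after T427, 0.04 after T408 and -0.30 after PW30, each ± 0.31 and none called.

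CD30L-Fc, T104 and PW30 raised 322 genes and lowered 120 in common, of 656 raised and 563 lowered by at least 1 of the 3. RELB, TRAF1, TNFRSF9 and LTA were among the raised genes, and EVA1A, GPR183 and SMIM43 among the lowered ones. CD30L-Fc and T104 shared 383 raised genes, against 26.2 for independent lists of these sizes, and 155 lowered genes, against 8.21. CD30L-Fc and PW30 shared 348 and 145 (27.8 and 11.2), and T104 and PW30 shared 367 and 165 (30.1 and 13.7). T427 and T408 shared 19 raised genes, against 0.0705. Of the 29 genes raised by T427 or T408, 28 were also raised by all 3 of CD30L-Fc, T104 and PW30. The exception, the RNA helicase gene DDX49, was not detected on the untreated, CD30L-Fc and T104 arrays. It passed after T427 (adjusted p = 0.0220), T408 (at least 1.06-fold, adjusted p = 0.0162) and PW30 (adjusted p = 0.00754) and not after CD30L-Fc (adjusted p = 0.141) or T104 (adjusted p = 0.998). DDX49 no longer passed after T427 without untreated replicate 2 or T427 replicate 2 or with the 4 arrays alone, nor after T408 without untreated replicate 2 or T408 replicate 1, nor in either with no filter on dim probes. Against T104 it was higher after T427 (adjusted p = 0.00292) and T408 (adjusted p = 0.00208) under every alternative that tested it, which leaves out detection on all 12 arrays. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.907 for CD30L-Fc and T104, 0.810 for CD30L-Fc and PW30, 0.816 for T104 and PW30 and 0.647 for T427 and T408. Unchanged groups simulated against the same untreated arrays gave 0.499, 0.5003, 0.498 and 0.499. The covariance was 0.133 for CD30L-Fc and T104 against a simulated 0.0133, and 0.0280 for T427 and T408 against 0.0133. In the 6 pairs of a stronger treatment with T427 or T408, r lay closer to its simulated value than in these 4, from 0.513 for T427 and PW30 to 0.583 for CD30L-Fc and T427 (simulated 0.499 and 0.501). Their covariance of 0.0419 to 0.0477 (simulated 0.0132 to 0.0133) lay further above its simulated value than that of T427 and T408. In the simulated experiments no pair shared more than 1 called gene, with a mean of at most 0.02. Those experiments held no changed genes and drew each gene independently, so few calls could arise. Their counts cannot show how many shared calls noise common to many genes would give. Every comparison uses the same 2 untreated arrays, too few to leave 2 in each part of a split, so part of the excess may come from them. With no filter on dim probes 76 genes were lowered by all 3, and with the 4 arrays of each comparison alone 63.

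At these shared genes T427 and T408 changed less, though the genes were selected for passing in the 3 other treatments, which favours larger changes there, and against the same untreated arrays, which favours changes of the same sign in all 5. The median log2 change of the 322 raised genes was 0.96, 0.99 and 0.98 after CD30L-Fc, T104 and PW30, and 0.24 and 0.25 after T427 and T408 (0.89, 0.91, 0.87, 0.21 and 0.22 with dim genes at their bounds). The median of the 120 lowered genes was -0.80, -0.81 and -0.80 after CD30L-Fc, T104 and PW30 and -0.25 and -0.24 after T427 and T408.

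Whether an antibody differed from the ligand was tested directly. T104 against CD30L-Fc called 0 of 8113 genes by limma, with 279 at an unadjusted p below 0.05 where 406 would be expected by chance. HOXB1 had the smallest p, at -0.91 ± 0.14 (adjusted p = 0.238), before SDHAF4 at 1.04 ± 0.19 and CRISPLD1 at -0.69 ± 0.13, and none of them passed. Over all genes the median 95% half-width was 0.32 and the largest difference 1.104, so smaller differences at single genes remain open. The count was 1 with every probe tested on its own and 15 with the adjustment over all 15 comparisons. The pooled cutoff of that adjustment does not limit false calls within this comparison.

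PW30 against CD30L-Fc called 13 genes. VASP, an actin regulator, was higher after PW30 by 1.31 ± 0.17 (adjusted p = 0.0185). NBPF9 was lower, at -2.06 ± 0.28 (adjusted p = 0.0185), as were CNST (-0.93 ± 0.13), LEPROT (-1.04 ± 0.17) and KMT2E, a chromatin regulator (-1.06 ± 0.17). Of the 13, 4 were higher and 9 lower, and 1088 genes had an unadjusted p below 0.05. With median scaling, which moved the median of all genes from -0.01 to -0.11, 1 was higher and 15 lower. Across genes, Spearman's rho between this difference and the genomic span of the gene was -0.237. The count was 0 with no filter, 1 with the 4 arrays alone, 6 with every probe tested on its own, 32 with probes detected on all 12 arrays, 34 with an offset of 50, 58 with the authors' processed values or no background correction, 95 with a variance trend and 99 with the adjustment over all 15 comparisons. Without PW30 replicate 1 or 2 it was 0 and 2, and without CD30L-Fc replicate 1 or 2 it was 2 and 8, and each of the genes named here lost its call in at least 1 of these.

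T427 was lower than CD30L-Fc at many of the genes the ligand raised. CD70 differed by -2.47 ± 0.21 (adjusted p = 2.57e-05) and TNFRSF9 by -2.44 ± 0.15 (adjusted p = 2.42e-06), and CD80 was at least 2.55-fold lower and SLAMF1 at least 3.96-fold lower. EVA1A (1.77 ± 0.17), CD93 (1.62 ± 0.17) and SMIM43 (1.35 ± 0.14) were higher. Of the 19 measured NF-kB genes 12 were lower and 0 higher (camera adjusted p = 2.68e-18, and adjusted p = 0.00254 with an estimated correlation). Of the 322 shared raised genes 218 were lower and 0 higher. Those genes were selected in part for a rise on these CD30L-Fc arrays, which favours that direction. In all 406 genes passed, 107 higher and 299 lower than after CD30L-Fc. The count was 225 with no filter on dim probes, 219 and 192 without CD30L-Fc replicate 1 or 2 and 189 and 204 without T427 replicate 1 or 2.

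T408 was also lower than CD30L-Fc at many genes, with TNFRSF9 at -2.45 ± 0.15 (adjusted p = 2.84e-06) and ZBTB32, a transcriptional repressor of lymphocytes, at -2.32 ± 0.14. CD80 was at least 2.92-fold lower, and EVA1A (1.97 ± 0.17), CD93 (1.54 ± 0.17) and SMIM43 (1.44 ± 0.14) were higher. Of 19 NF-kB genes 13 were lower and 0 higher (camera adjusted p = 2.97e-18, and adjusted p = 0.00255 with an estimated correlation). Of the 322 shared raised genes, selected in part for a rise on these CD30L-Fc arrays, 218 were lower and 0 higher. In all 432 genes passed, 129 higher and 303 lower. The count was 250 with no filter on dim probes, 225 and 213 without CD30L-Fc replicate 1 or 2, 196 without T408 replicate 1 (36 higher, 160 lower) and 226 without T408 replicate 2.

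Between antibodies, T104 was higher than T427 and T408 at many of the genes T104 raised. EBI3 was higher after T104 than after T427 by 2.60 ± 0.14 (adjusted p = 1.17e-06) and ZBTB32 by 2.57 ± 0.14, and CXCL10, an interferon-inducible chemokine, was at least 2.25-fold and GPR84 at least 3.32-fold higher. GPR183 was lower, at -1.41 ± 0.13. Among the 19 NF-kB genes 11 were higher and 0 lower (camera adjusted p = 1.26e-18, and adjusted p = 0.00241 with an estimated correlation). Of the 322 shared raised genes, selected in part for a rise on these T104 arrays, 219 were higher. In all 422 genes passed, 302 higher and 120 lower after T104. The count was 259 with no filter on dim probes, 218 and 245 without T104 replicate 1 or 2 and 246 and 225 without T427 replicate 1 or 2.

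T104 against T408 called 483 genes, 323 higher and 160 lower after T104. ZBTB32 was higher by 2.66 ± 0.14 (adjusted p = 9.79e-07), CD80 at least 3.38-fold and GPR84 at least 3.80-fold, and EVA1A was at least 3.11-fold lower. In the NF-kB list of 19 genes 13 were higher and 0 lower (camera adjusted p = 6.61e-19, and adjusted p = 0.00231 with an estimated correlation). Of the 322 shared raised genes, selected in part for a rise on these T104 arrays, 229 were higher. With median scaling, which moved the median of all genes from -0.03 to -0.13, 212 were higher and 260 lower. The count was 277 with no filter on dim probes, 252 and 261 without T104 replicate 1 or 2, 234 without T408 replicate 1 (182 higher, 52 lower) and 276 without T408 replicate 2.

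T427 against PW30 called 607 genes, 242 higher and 365 lower after T427. CD70 was lower by -2.71 ± 0.21 (adjusted p = 1.16e-05) and EBI3 by -2.56 ± 0.14, and GPR84 was at least 3.90-fold lower. ARID5B was higher by 1.52 ± 0.13 and ANKRD20A1 by 1.69 ± 0.21. Of the 19 measured NF-kB genes 11 were lower and 0 higher (camera adjusted p = 5.48e-14, and adjusted p = 0.00543 with an estimated correlation). Of the 322 shared raised genes, selected in part for a rise on these PW30 arrays, 225 were lower. With median scaling 274 were higher and 239 lower. The count was 327 with no filter on dim probes, 273 and 325 without T427 replicate 1 or 2 and 328 and 369 without PW30 replicate 1 or 2.

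T408 against PW30 called 542 genes, 212 higher and 330 lower after T408. ZBTB32 was lower, at -2.54 ± 0.14 (adjusted p = 1.5e-06), as were GPR84 (at least 4.46-fold) and CD80 (at least 2.81-fold), and ARID5B was higher by 1.65 ± 0.13. Of 19 NF-kB genes 10 were lower and 0 higher (camera adjusted p = 1.82e-16, and adjusted p = 0.00343 with an estimated correlation). Of the 322 shared raised genes, selected in part for a rise on these PW30 arrays, 223 were lower. With median scaling, which moved the median of all genes from 0.03 to 0.16, 463 were higher and 205 lower. The count was 292 with no filter on dim probes, 343 with the 4 arrays alone, 277 and 260 without T408 replicate 1 or 2 (72 higher and 188 lower in the latter) and 326 and 290 without PW30 replicate 1 or 2.

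T104 against PW30 called 26 genes, 18 higher and 8 lower after T104. NBPF9 was higher, with a 95% interval of 1.40 to 2.60 (adjusted p = 0.0355), PHACTR2, a phosphatase and actin regulator, by 1.38 ± 0.22, SRPK2, a kinase of splicing factors, by 1.27 ± 0.23 and LEPROT by 1.16 ± 0.17. ALG1, an enzyme of protein glycosylation, was lower, at -0.78 ± 0.14, as was the histone gene H2AB2 (-0.77 ± 0.14). In all, 977 genes had an unadjusted p below 0.05. With median scaling 13 were higher and 3 lower, and Spearman's rho with genomic span was 0.209. The count was 1 with the 4 arrays alone, 2 with no filter on dim probes, 63 with the authors' processed values or no background correction, 81 with a variance trend and 109 with the adjustment over all 15 comparisons. It was 0 without T104 replicate 1, PW30 replicate 1 or PW30 replicate 2 and 13 without T104 replicate 2, and every gene named here lost its call in at least 1 of these.

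T427 against T408 called 0 of 8113 genes by limma, with 386 at an unadjusted p below 0.05 where 406 would be expected by chance. TRIM45, ZBTB45 and SLC7A6OS had the smallest p, at 0.68 ± 0.14, -0.94 ± 0.21 and -0.82 ± 0.19, each with an adjusted p of 0.998. They were detected in 1 of the 2 groups, with folds of at least 1.23, 1.18 and 1.23. Over the 322 shared raised genes the median difference was -0.00, with a median 95% half-width of 0.31 and a largest difference of 1.06. Adjusted over all 15 comparisons, 7 genes were called, under a pooled cutoff that does not limit false calls within this comparison.

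T427 and T408 did not reach a uniform fraction of the log2 change after the 3 stronger treatments at every gene. This comparison was added after the data had been seen. It used 148 genes raised by all 3 of CD30L-Fc, T104 and PW30 with a mean change of at least 2-fold. The mean log2 change after T427 and T408 was fitted across them as a fraction of that after the 3 others. Least squares through the origin, which weights the largest changes most, gave a pooled fraction of 28.1%, taken as fixed below. At 32 genes the fraction differed from this value by limma (adjusted p below 0.05), 20 above and 12 below. RELB reached 51.6%, TRAF1 50.2%, IL4I1 51.9% and CXCR4 65.0%. EBI3 reached 12.98%, CD70 3.70% and ZBTB32 -0.911%. On the linear scale, where departures were not tested, the fractions were 26.3% for RELB, 22.97% for TRAF1, 28.7% for IL4I1 and 50.6% for CXCR4, and 5.00% for EBI3, 1.40% for CD70 and -0.198% for ZBTB32. These genes were singled out after their values were seen.

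**Figure D3:**
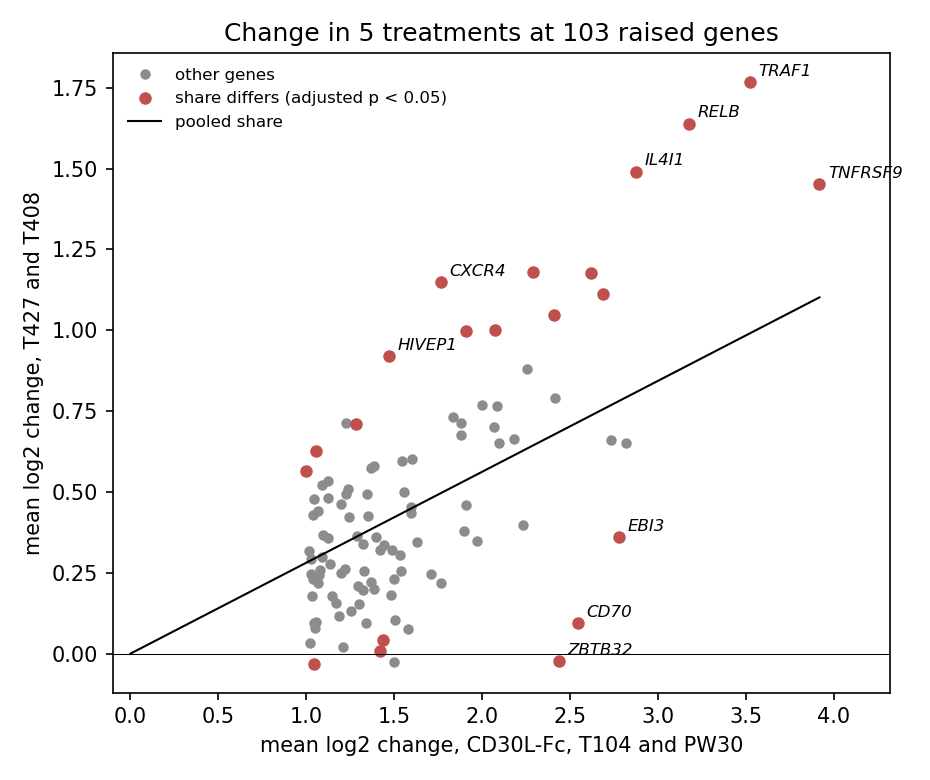
Mean log2 change after T427 and T408 (vertical axis) against that after CD30L-Fc, T104 and PW30 (horizontal axis), each against untreated cells, at the 103 of 148 raised genes detected on both untreated arrays. The line marks the pooled fraction of the log2 change of 28.1%, and red points are the 21 genes that depart from it, with RELB (51.6%) above and CD70 (3.70%) below.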

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

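The counts in this part were not among the comparisons planned before the data were seen, and no explanation of them was tested. Of the probes that passed the filter, 1597 carry no single gene in the probe annotation and were left out of the comparisons above. Tested in the same way with limma, with the adjustment within each comparison, these probes gave calls in every treatment against untreated cells. The counts were 91 after CD30L-Fc (70 higher, 21 lower), 111 after T104 (85 higher, 26 lower), 143 after PW30 (103 higher, 40 lower), 3 after T427 and 5 after T408, all of the last 8 calls higher. The largest rise was that of the same probe in all 5 treatments, by a log2 of 3.25 after CD30L-Fc, 3.12 after T104, 2.72 after PW30, 1.60 after T427 and 1.75 after T408, each ± 0.21 (SE, n = 2).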

How the results depend on the processing

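The fit without the PW30 arrays was chosen only after the data had been seen. No named called gene and no called gene list turned direction. Under the alternatives that keep both arrays of each group compared, 135 counts of called genes stayed within 1.5 times the main count and 40 moved further. These include the fit without the PW30 arrays. With 1 array left out 18 stayed and 42 moved, and the lone array is assumed to vary like the other groups. Of the adjusted p of gene lists 419 stayed on the same side of 0.05, 14 newly passed and 7 no longer passed, and of the changes of named genes 3598 stayed, 6 newly passed and 261 no longer passed. With 1 array left out 1103 of the changes of named genes stayed, 1 newly passed and 264 no longer passed. The cause of these moves was not tested. A block for the BeadChip slide was not run, since the files used show no slide. Values below are numbers of called genes, and treatments named alone are against untreated cells. The replicate block left 652, 696, 23, 20 and 831 called genes for CD30L-Fc, T104, T427, T408 and PW30. Replicate numbers did not pair the groups, as duplicate differences correlated across genes between groups by -0.0758 to 0.107.

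No filter on dim probes, which tests more genes, gave 500 (T104), 10 (T427), 13 (T408), 546 (PW30), 225 (T427 against CD30L-Fc), 250 (T408 against CD30L-Fc), 0 (PW30 against CD30L-Fc), 259 (T104 against T427), 277 (T104 against T408), 2 (T104 against PW30), 327 (T427 against PW30), 292 (T408 against PW30) and 76 genes lowered by all 3 of CD30L-Fc, T104 and PW30. Only the 4 arrays of the 2 groups gave 402 (CD30L-Fc), 487 (T104), 5 (T427), 9 (T408), 490 (PW30), 1 (PW30 against CD30L-Fc), 1 (T104 against PW30), 343 (T408 against PW30) and 63 lowered by all 3. Adjustment over all 15 comparisons gave 63 (T427), 72 (T408), 15 (T104 against CD30L-Fc), 99 (PW30 against CD30L-Fc), 109 (T104 against PW30) and 7 (T427 against T408). Its cutoff is pooled over the comparisons, so part of these added calls may be false. For T408, PW30 against CD30L-Fc and T104 against PW30, the authors' processed values gave 34, 58 and 63, no background correction gave 34, 58 and 63, and a trend and robust prior gave 41, 95 and 81. Every probe on its own gave 1 (T104 against CD30L-Fc) and 6 (PW30 against CD30L-Fc). For PW30 against CD30L-Fc an offset of 50 gave 34 and detection on all 12 arrays 32, and for T104 against PW30 median scaling gave 16. Of the gene lists, an estimated correlation left 1 called for T427 and 1 for T408, and fry called 4 and the authors' values 6 for T408.

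Leaving out 1 array gave 372 to 566 (CD30L-Fc), 425 to 554 (T104), 8 to 22 (T427), 14 to 31 (T408), 562 to 712 (PW30), 0 to 1 (T104 against CD30L-Fc), 189 to 219 (T427 against CD30L-Fc), 196 to 226 (T408 against CD30L-Fc), 0 to 8 (PW30 against CD30L-Fc), 218 to 246 (T104 against T427), 234 to 276 (T104 against T408), 0 to 13 (T104 against PW30), 273 to 369 (T427 against PW30) and 260 to 326 (T408 against PW30). Of the named called genes, 49 of 71 (CD30L-Fc), 54 of 70 (T104), 5 of 14 (T427), 7 of 13 (T408) and 53 of 74 (PW30) passed under every alternative that tested them. Detection on all 12 arrays leaves dim genes untested. Without the PW30 arrays the counts were 688 (CD30L-Fc), 752 (T104), 21 (T427) and 21 (T408). Signal over background limits the change of dim genes, which is given as a bound.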

Other observations

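The test of gene span and the test of bright probes were set before their results were seen, and all other tests in this part were chosen after. Some genes reached a large fraction of the stronger response after T427 and T408. NFKBIZ, an atypical NF-kB inhibitor, changed by 52.4% of the mean log2 change after CD30L-Fc, T104 and PW30, NFKB2 by 51.6%, the transcription factor gene HIVEP1 by 62.6%, and DDIT4, an inhibitor of mTOR signalling, by 56.6%. Others reached almost none of it, among them LSP1, an actin-binding protein of leukocytes (2.99%), PIK3C2B, a lipid kinase (0.649%), and ADGRE5, an adhesion receptor (-2.93%). On the linear scale the fractions were 36.3% for NFKBIZ, 32.7% for NFKB2, 50.4% for HIVEP1 and 47.8% for DDIT4. They were 2.24% for LSP1, 0.415% for PIK3C2B and -1.78% for ADGRE5. These genes were chosen after their values were seen.

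Against the mean of CD30L-Fc and T104, PW30 differed at 55 genes by limma, 15 higher and 40 lower. Lower were EP300, a histone acetyltransferase (-0.97 ± 0.15), CYLD, a deubiquitinase that restrains NF-kB (-1.01 ± 0.18), and ATP8A1, a phospholipid flippase (-0.84 ± 0.10). Higher were LY6E, an interferon-inducible surface protein (0.71 ± 0.11), and DOK2, an adaptor of tyrosine kinases (0.79 ± 0.15). These genes, too, were chosen after their values were seen. This contrast was not repeated under the alternatives or with 1 array left out. PW30 against CD30L-Fc and T104 against PW30, which use the same arrays, each called 1 gene with the 4 arrays alone. Their counts also fell with 1 array left out, as given above, so the calls named here may depend on single arrays.

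The first pattern weighed is that PW30 departs from CD30L-Fc and T104 at part of the genes. A stronger or weaker form of the same response is argued against at 195 genes chosen without the PW30 arrays. There the PW30 change regressed on the mean of the 2 others with a slope of 0.979 (SE across genes 0.0162). Genes are not independent replicates, so this SE understates the uncertainty. The untreated arrays shared by both changes also draw them together. A bias with gene length may contribute, since Spearman's rho across genes between the PW30 difference and genomic span was -0.239, larger in size than in any difference between duplicates (0.137 at most). Variation that also occurs between duplicates cannot be told apart from an effect of the antibody, since its largest correlation with the PW30 difference, 0.142 in size, lay between the values set for and against it. An effect of PW30 itself stays open and untested, since the same 2 arrays carry the antibody and any handling they share.

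The second pattern weighed is that T427 and T408 reached different fractions of the stronger response at different genes on the log2 scale, the only scale on which departures were tested. A floor at dim genes is argued against as the whole cause, since 20.4% of the 103 genes detected on both untreated arrays departed from the pooled fraction. That fraction was fitted over all 148 genes, so the dim genes helped to set it. Saturation of bright probes is argued against in the same way, since 21.2% of the 146 genes under a log2 level of 14 departed. It may be that NF-kB subunits and regulators reach a larger fraction than other genes, with medians of 43.1% in 10 genes and 25.5% in 138 (two-sided permutation p = 0.0158). On the linear scale, required as well only after that p was known, the medians were 24.3% and 16.5% (permutation p = 0.144). A larger fraction therefore cannot be told apart from the scale on which it is measured. Both permutations shuffled genes, which are not independent replicates. Their p-values hold no variation between arrays and may be too small.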
